A study of Mus musculus with 6 samples.

How the data were processed

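The series holds liver RNA sequencing of C57BL/6 mice, with 3 sham-operated livers and 3 livers after ischemia and reperfusion (IR), a procedure in which blood flow to the liver is blocked and then let back in. All 6 samples carry the genotype label WT and titles with the word flox, and the IR titles give a time of 3 h, without saying whether this counts from the start of reperfusion. Livers lacking Ncor1 were not analysed here. The labels give separate samples in each group and do not say more of the animals, so p-values measure the spread between these samples. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a SMARTER mRNA kit.

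The deposited counts are whole-number reads per gene symbol, 1 column per liver, for 22599 genes, of which 2191 were at 0 in every library. Per the submitters' processing notes, the builds GRCm38, mm10 and hg38 were named, with no role given to any. The aligner, the counting tool, the use of strand and the treatment of reads that match several genes are not given in the sources used here. The deposited FPKM table covers the same genes and livers. For 101792 of its 101793 values above 0, the FPKM value equalled the deposited count divided by 1 length per gene and by the column total, within a relative tolerance of 1e-06, so it is the same measurement on another scale and not an independent one. Gene lengths used below came from this relation.

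Total counts ran from 34332919 to 40905884 per library. A count of 0 allows up to 3 counts, which is 0.0733 to 0.0874 CPM (counts scaled to library size) per library, and this limit covers counting error only. No pair of libraries within a group agreed within sampling noise: the chi-square per gene was 46.7 or more, so each library counted as 1 replicate.

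Genes with enough counts by edgeR's filterByExpr (13101 genes) were compared between IR and sham with edgeR's quasi-likelihood test, 2-sided, with TMM scaling, no covariate and Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 fold changes were taken as the log2 fold change divided by the root of the F statistic. Levels are TMM-scaled CPM as mean ± SD over 3 livers. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. On simulated data for the IR against sham comparison, with 197 changed genes among 12880 tested, edgeR recovered 84.7% of 4-fold and 15.2% of 2-fold changes, with 6.67% false calls. DESeq2 recovered 91.8% and 33.3%, with 21.7% false calls. The length correction was tested on simulated data too and brought a Spearman correlation of -0.587 between fold change and length to -0.0019 over 12872 genes.

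Before the data were examined, 37 gene lists were fixed, 20 of pathways and 17 of cell types, zones, mitochondrially encoded genes and sex-linked genes. Of their 670 entries, 658 matched a gene, 1 of them through an older symbol and 13 through mitochondrial symbols. Mx1, Mx2, Trac, Ighm, Iglc2, Prss2, Try4, Cela3b, Cpb1, Pnlip, Clps and Amy2a5 were not in the table used here. Lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 36 lists with at least 2 tested members. Counts of called members are given over all genes and adjusted over the list alone. Genes named in the text were chosen by a rule fixed at the same time: Ncor1, Rela and Nfkb1 as genes of the series title; the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups; the 2 called members of each pathway list with the largest change (1 for the other lists), or the member with the smallest p where none was called; and, per list, the called member with the largest change against the direction of most called members. This gave 65 genes, of which some are not reported here. Other list members named in the text were chosen after their values were seen. Coordinates are from NCBI RefSeq for GRCm38.p6, which gave 21963 of the 22599 symbols.

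Alternatives fixed before the data were examined were DESeq2, limma-voom, RLE scaling, library size without scaling factors, other low-count filters, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library. Camera with an estimated correlation and limma's fry were the alternatives for the lists. Corrections for trends with gene length and GC content, with a lowess span of 0.5 per library, and a fit without mitochondrially encoded genes were added after seeing the data. The GC content, from GENCODE M21 transcripts, was known for 96.5% of the tested genes.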

Results

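Liver RNA was compared between sham-operated mice and mice after ischemia and reperfusion, 3 livers per group, all labelled wild type. The series title names Ncor1, a nuclear receptor corepressor, and the NF-kB subunit p65, the product of Rela. The comparison here covers what IR did in livers with intact Ncor1. Total counts were 39777752, 40905884 and 40369947 in sham replicates 1 to 3 and 34332919, 36459643 and 38275111 in IR replicates 1 to 3.

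After IR, the livers carried far more mRNA of single genes such as Mt2, Cxcl1 and Lcn2 and less of others such as Dbp, Kdr and Acaca. Mt2, a metallothionein, rose from 13.4 ± 10.3 to 1951 ± 548 CPM (SD, n = 3), a 146-fold change. Its log2 fold change of 7.19 was 7.89 without sham replicate 1 and 6.45 with the trend of gene length taken out, so the size of the rise is less certain than its direction. Cxcl1, a chemokine that attracts neutrophils, rose 66.9-fold to 216 ± 48.7 CPM, and Lcn2, an iron-carrier-binding acute-phase protein, rose 64.0-fold to 220 ± 113 CPM. Dbp, a clock-controlled transcription factor, was 9.36-fold lower than the 121 ± 40.3 CPM of sham livers (SE 0.33 on the log2 scale). Kdr, the endothelial VEGF receptor, was 4.95-fold lower, at 8.20 ± 1.75 against 40.7 ± 12.7 CPM.

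**Figure D1:**
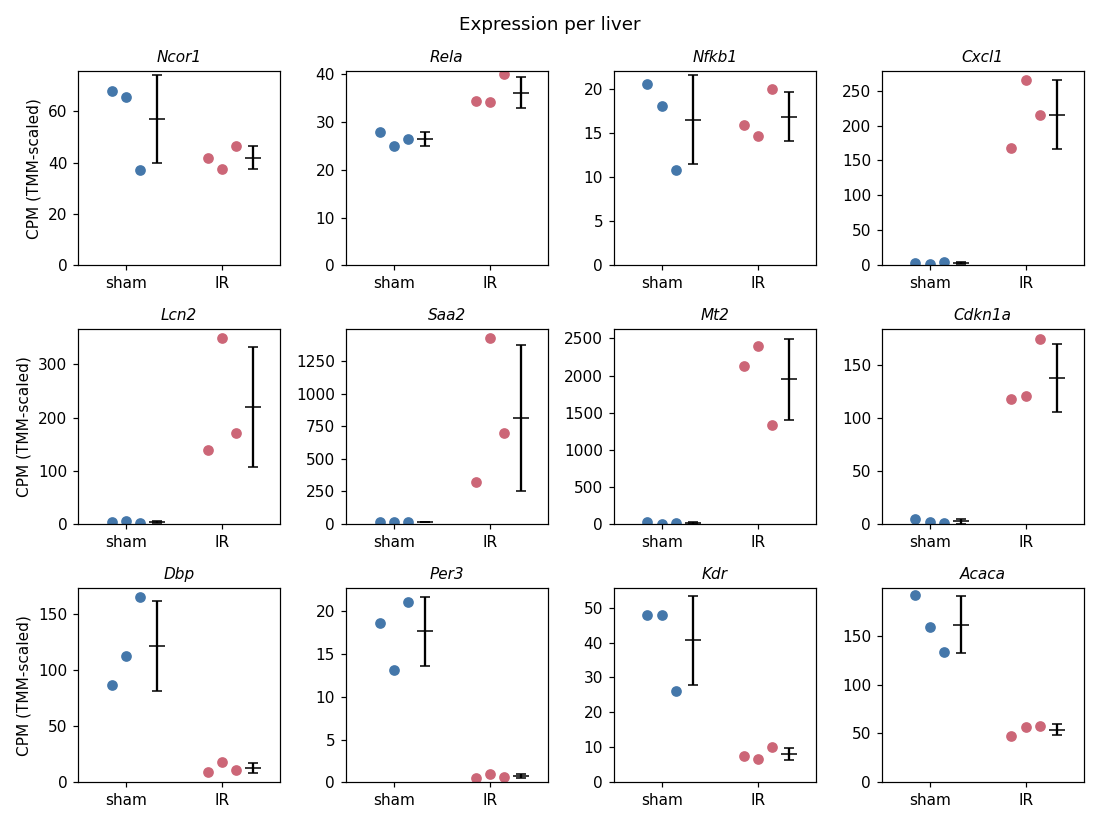
TMM-scaled CPM of 12 named genes in each liver (points, blue for sham and red for IR), with the mean and SD of 3 livers (black bars), each panel with its own linear axis from 0. Cxcl1, Lcn2, Saa2, Mt2 and Cdkn1a lay higher in each IR liver than in each sham liver and Dbp, Per3, Kdr and Acaca lower, whereas the groups overlapped at Ncor1 and Nfkb1.

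The genes of the title themselves did not pass the test. Ncor1 (chromosome 11, 62315663 to 62457414) was at 56.9 ± 17.1 CPM in sham and 42.0 ± 4.50 CPM in IR (log2 fold change -0.44, SE 0.25, edgeR adjusted p = 0.273). The groups overlapped through sham replicate 3, at 37.2 CPM against 67.9 and 65.6 CPM in sham replicates 1 and 2. The IR livers were at 42.0, 37.5 and 46.5 CPM. At 11483 bp Ncor1 is among the longest genes, whose median log2 fold change was -0.25. Its locus overlaps Ttc19. Rela (chromosome 19, 5637442 to 5648134) was at 26.5 ± 1.47 and 36.2 ± 3.30 CPM (log2 fold change 0.45, SE 0.18, adjusted p = 0.139), with each IR liver above each sham liver. Nfkb1 (chromosome 3, 135584655 to 135691969), which encodes another NF-kB subunit, was at 16.5 ± 5.02 and 16.8 ± 2.79 CPM (log2 fold change 0.03, SE 0.27, adjusted p = 0.949).

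Over all genes, 585 were higher and 489 lower after IR at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 494 and 405 of them by more than 2-fold. The 6 largest rises by the fixed rule were Mt2, Cxcl1, Lcn2, Saa2 (log2 fold change 5.82, SE 0.54), Cdkn1a (5.78, SE 0.61) and Mt1 (5.48, SE 0.68). The 6 largest falls were Dbp (-3.23, SE 0.33), Arrdc3 (-2.67, SE 0.32), Hhex (-2.57, SE 0.56), Anks4b (-2.54, SE 0.24), Inhbe (-2.46, SE 0.44) and Klhdc7a (-2.38, SE 0.42). Hhex lost its call without sham replicate 1, IR replicate 1 or IR replicate 3, Inhbe without IR replicate 1 or 2, and Klhdc7a without IR replicate 1 (adjusted p up to 0.0984). With scaling by library size alone, the calls became 352 higher and 3159 lower, or 10% higher against 54.5%. The median log2 fold change of all genes then moved to -0.51, so directions are relative to the TMM scaling. The counts of higher and lower genes were 388 and 173 without sham replicate 1, 192 and 90 without sham replicate 2, 1260 and 1187 without sham replicate 3, 270 and 97 without IR replicate 1, 234 and 65 without IR replicate 2, and 904 and 769 without IR replicate 3.

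Libraries within a group also differed. The first principal component of log2 CPM carried 52.0% of the variance and parted the groups, and the second carried 24.1% and set sham replicate 3 apart. Mitochondrially encoded genes took 6.08, 4.54 and 4.45% of the counts in the sham livers and 19.7, 12.6 and 8.17% in IR replicates 1 to 3. Fold changes fell with gene length across genes (Spearman rho -0.296 over 13101 genes, which are not independent replicates), from a median log2 fold change of 0.45 in the shortest eighth of genes to -0.25 in the longest. With the length trend of each library taken out, a correction chosen after seeing the data, 600 genes were higher and 376 lower, and 811 of the calls kept their sign and call.

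**Figure D2:**
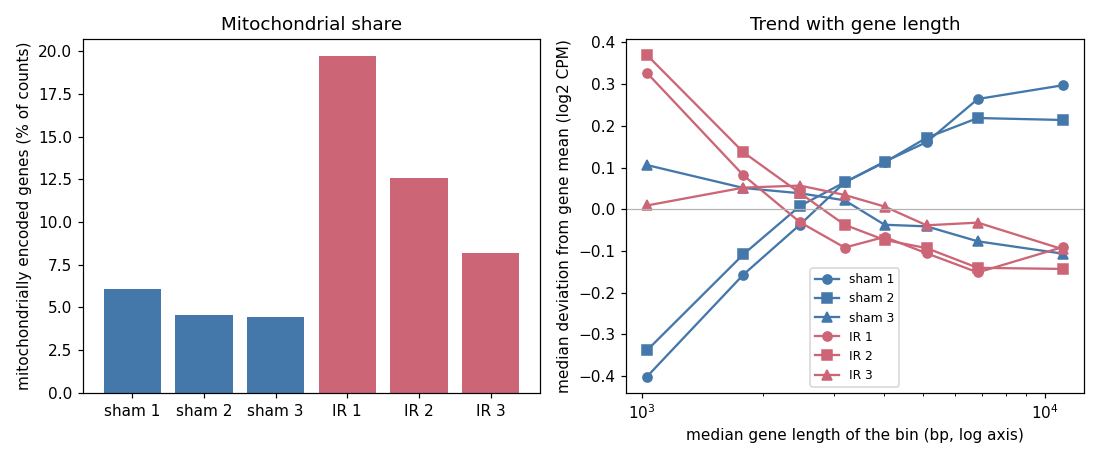
Left, the share of counts in mitochondrially encoded genes per library (bars from 0, in percent), from 4.45% in sham replicate 3 to 19.7% in IR replicate 1. Right, the median deviation from each gene's mean log2 CPM in 8 bins of gene length (log axis, bp), with 1 line per library: sham replicates 1 and 2 leaned to long genes and IR replicates 1 and 2 to short ones. Sham replicate 3 leaned to short genes too, and lay above IR replicate 3 in the shortest bin (0.106 and 0.0092).

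**Figure D3:**
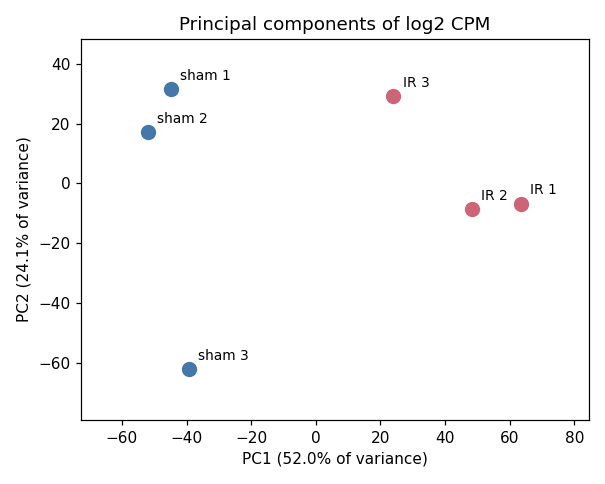
The 6 libraries on the first and second principal components of log2 CPM (axes in component units, blue for sham and red for IR). The first axis (52.0% of variance) parts the groups, and sham replicate 3 lies lowest on the second (24.1%).

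Of the 37 lists, 36 could be tested, and 11 passed camera with the preset correlation, 9 higher and 2 lower. None passed with an estimated correlation, where the adjusted p of those 11 ran from 0.220 to 0.669. Other lists passed camera only in other settings. Without sham replicate 1, cytokines, fatty-acid oxidation, p53 and coagulation genes passed. Without IR replicate 2, p53 and coagulation genes passed. Coagulation genes also passed without sham replicate 2, and red-cell markers without IR replicate 1 (lowest adjusted p 0.0125). On log2(FPKM + 1) and log2(FPKM + 0.1), cytokines passed (camera adjusted p = 0.0379 and 0.039), as did p53 genes (0.00812 and 0.0126). With library size alone, p53 (camera adjusted p = 0.0197) and coagulation genes (0.0469) passed. Among acute-phase genes 14 of 25 tested members rose and none fell (19 adjusted over the list alone). Their median log2 fold change was 1.44 (camera adjusted p = 8.78e-11, and adjusted p = 0.220 with an estimated correlation). Beside Lcn2 and Saa2, Socs3, a feedback inhibitor of cytokine signalling, rose by 4.09 on the log2 scale (SE 0.26), and Orm1, Hp and Serpina3n rose by 1.46, 1.44 and 2.19. Saa1 and Saa2, and Orm1 to Orm3, are close copies, so how their shared reads were divided is uncertain. C3, at -0.38 (adjusted p = 0.356), did not pass.

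Among NF-kB pathway and feedback genes, 9 of 26 rose and 1 fell (11 and 1 adjusted over the list alone). Their median log2 fold change was 0.53 (camera adjusted p = 0.000254, and adjusted p = 0.220 with an estimated correlation). On log2(FPKM + 1), without TMM scaling, it was -0.037 against -0.36 for all genes, and the list still passed camera (adjusted p = 0.00044). Nfkbiz (2.58, SE 0.41) and Bcl3 (2.45, SE 0.25), atypical IkB proteins, rose most, and Nfkbia, the classical inhibitor, rose by 1.09 (SE 0.24). Tnfaip2 fell by 1.44 (SE 0.27), a call lost without sham replicate 2, IR replicate 1 or IR replicate 2 (highest adjusted p 0.0823). Cxcl1 was the only called gene of 11 tested cytokines and chemokines (1 adjusted over the list alone), whose camera adjusted p was 0.109. Of 28 immediate-early genes, 7 rose and none fell (10 adjusted over the list alone), led by Gadd45b (3.55, SE 0.69) and Nr4a2 (2.70, SE 0.65). Nr4a2 rested on 41 counts over the sham livers and 165 over the IR livers. While 26 members lay above 0, Jun (-0.20) and Egr1 (-0.29) lay below, and Fos (2.13, adjusted p = 0.132) was not called. Jun was at 143 CPM in sham replicate 1 against 17.4 and 10.4 CPM in sham replicates 2 and 3, and Egr1 at 152 against 11.2 and 43.3 CPM. The list's median was 1.22 (camera adjusted p = 8.36e-08, and adjusted p = 0.476 with an estimated correlation). Leaving out IR replicate 1 raised the adjusted p of Gadd45b to 0.0734. Leaving out 1 of 3 libraries (sham replicate 1, sham replicate 2 or IR replicate 1) ended the call of Nr4a2, with an adjusted p of up to 0.136. Over the single leave-outs, the log2 fold change ran from 2.98 to 4.72 for Gadd45b and from 1.915 to 3.15 for Nr4a2. Junb and Fosl2 also rose, by 2.17 and 1.87.

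Neutrophil markers rose: 6 of 9 tested members were called, none fell (7 adjusted over the list alone), and the median log2 fold change was 3.48 (camera adjusted p = 8.36e-08, and adjusted p = 0.220 with an estimated correlation). Mmp8, a neutrophil collagenase, had 4 counts over the 3 sham livers and 130 over the 3 IR livers (log2 fold change 5.53, SE 0.69), and the alarmin genes S100a8 and S100a9 rose by 3.48 and 4.17. Among sinusoidal endothelial markers, 2 of 16 were lower and 1 higher (6 and 1 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.0117, and adjusted p = 0.669 with an estimated correlation). These markers move together (estimated correlation 0.742) and also varied within the sham group. Their median in sham replicate 3 was -0.957 on the log2 scale relative to the other sham livers. That list no longer passed without sham replicate 2 or IR replicate 3 (adjusted p up to 0.1). Kdr fell by 2.31 (SE 0.29), whereas Lyve1, also a lymphatic marker, rose by 1.65 (SE 0.36), a call lost without IR replicate 1 or 2 (adjusted p up to 0.0925). B-cell markers had a median of -1.39 with 0 of 4 called by edgeR (2 lower adjusted over the list alone; camera adjusted p = 0.0448, and adjusted p = 0.476 with an estimated correlation). They did not pass without sham replicate 3 (adjusted p = 0.160), and Pax5 was at -2.22 (adjusted p = 0.102).

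Other cell types gave few calls. Of 10 monocyte markers 1 rose, Plac8 (1.02, SE 0.26), against a list median of -0.52, and of 11 Kupffer-cell markers 1 fell, Adgre1 (-1.34, SE 0.31; 1 each adjusted over the list alone). Each of these 2 calls was lost without sham replicate 1, sham replicate 2, IR replicate 1 or IR replicate 2 (adjusted p up to 0.177). Of 15 stellate-cell and fibroblast markers 1 fell (0 adjusted over the list alone), Reln (-1.06, SE 0.28), a call that ended with the length correction (-0.81, SE 0.27, adjusted p = 0.103). It was also lost without sham replicate 1, sham replicate 2, IR replicate 1 or IR replicate 3 (adjusted p up to 0.148). No marker was called among 8 of cholangiocytes (Krt19 0.84, adjusted p = 0.389), 8 of T and NK cells (Ccl5 1.14, adjusted p = 0.117), 4 of platelets (Ppbp 0.99, adjusted p = 0.159) and 2 of pancreatic acinar cells (Cela1 0.78, adjusted p = 0.0923). Adjusted over the list alone, 1 acinar gene was higher and the other 3 lists gave 0 calls. Hba-a1 and Hba-a2, near-identical globin genes, were the 2 higher members of 5 red-cell markers (2 adjusted over the list alone), and the call of Hba-a2 (1.22, SE 0.32) ended with the length correction (0.61, adjusted p = 0.141) and without sham replicate 1 or 2 or IR replicate 1 or 2 (adjusted p up to 0.185). No mesothelial marker had enough counts to be tested. The 5 sex-linked genes gave no call (0 adjusted over the list alone), and Ddx3y, on chromosome Y, was at 67.3 ± 4.05 and 107 ± 47.0 CPM.

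Single genes of the stress lists were called. Of 19 tested NRF2 targets, 4 rose (5 higher and 1 lower adjusted over the list alone): Mt2, Mt1, Srxn1 (2.14) and Hmox1 (1.40). Mt2 (7.19) and Mt1 (5.48) had the largest rises, and the list was not tested without them. Although 14 members lay above 0, Nqo1 (0.25), Gclm (0.23), Txnrd1 (0.12) and Gsr (0.31) were not called. Osgin1 was at -2.22 (edgeR adjusted p = 0.0679). The list's median was 0.31 (camera adjusted p = 0.00683, and adjusted p = 0.476 with an estimated correlation). It lay below 0 when scaled by library size alone, where all genes moved lower and the list still passed camera (adjusted p = 0.00195). In the p53 and apoptosis list 4 of 24 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.109). Cdkn1a, a cell-cycle inhibitor, rose 55.0-fold (log2 fold change 5.78, and 6.76 without sham replicate 1) and Trp53inp1 5.80-fold, whereas Bbc3, a pro-apoptotic gene, fell by 1.86 (SE 0.42), a call lost without sham replicate 2 or any single IR replicate (adjusted p up to 0.120). Of 22 hypoxia genes, 2 rose, Ndrg1 (2.32, SE 0.24) and the glucose transporter gene Slc2a1 (1.38, SE 0.22), and Ero1a fell by 1.35 (SE 0.31; 3 and 1 adjusted over the list alone; camera adjusted p = 0.406). The call of Ero1a was lost without sham replicate 1, sham replicate 2, IR replicate 1 or IR replicate 2 (adjusted p up to 0.139). Ddit4 (3.70, SE 0.50) and Sdf2l1 (1.05, SE 0.24) were the 2 called of 24 unfolded-protein and integrated-stress genes (3 adjusted over the list alone; camera adjusted p = 0.463). Sdf2l1 was no longer called with the length correction (0.70, SE 0.26, adjusted p = 0.129), nor without sham replicate 1, sham replicate 2 or IR replicate 2 (adjusted p up to 0.116). Hspb8 (1.43, SE 0.20) was the 1 called of 22 heat-shock genes (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.404). Of 22 interferon-stimulated genes, 4 fell and none rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0612), namely Oasl1, Oasl2 (-1.14, SE 0.29), Oas1a (-1.10, SE 0.25) and Ddx58. That list passed with the length correction (camera adjusted p = 0.0349) and without sham replicate 3 or IR replicate 2 (lowest adjusted p 0.0182). It did not pass with an estimated correlation (camera adjusted p = 0.495). The calls of Oasl2 and Oas1a were lost without sham replicate 1 or 2 or without IR replicate 1 or 2, and that of Oasl2 also without IR replicate 3 (adjusted p up to 0.189).

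Single metabolic genes were called in either direction. Of 21 gluconeogenesis and amino-acid catabolism genes, 4 rose and none fell (8 adjusted over the list alone). The list's median was 0.35 (camera adjusted p = 0.0067, and adjusted p = 0.220 with an estimated correlation). It lay below 0 when scaled by library size alone, where all genes moved lower and the list still passed camera (adjusted p = 0.00152). The list did not pass without IR replicate 3 (adjusted p = 0.0553). Sds and Tat, which break down serine and tyrosine, rose by 2.41 (SE 0.27) and 2.03 (SE 0.39), and the call of Tat was lost without IR replicate 2 (adjusted p = 0.0524). Among 20 lipogenesis genes, 3 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.463). Acaca, which makes malonyl-CoA, fell by 1.58 (SE 0.21), Pklr by 1.18 and Acly by 1.07, whereas Lpin1 rose by 1.45 (SE 0.29; lost without sham replicate 2 or IR replicate 2, adjusted p up to 0.0904). Of 23 cholesterol-synthesis genes, 2 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.726). Hmgcs1, an early enzyme gene of the pathway, rose by 1.63 (SE 0.40), a call lost without sham replicate 1 or 2 or IR replicate 1 or 2 (adjusted p up to 0.123). Ppargc1a (2.40, SE 0.27), a coactivator of fasting metabolism, and Angptl4 (1.77, SE 0.42) were the 2 called of 27 fatty-acid oxidation genes (2 adjusted over the list alone; camera adjusted p = 0.219). Angptl4 was no longer called with the length correction (1.61, SE 0.45, adjusted p = 0.0632), nor without sham replicate 2, IR replicate 1 or IR replicate 2 (adjusted p up to 0.108).

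Of 18 bile-acid genes, Cyp7a1, the rate-limiting enzyme of bile-acid synthesis, fell by 1.67 (SE 0.43) and Baat rose by 0.86 (SE 0.20; 1 and 1 adjusted over the list alone; camera adjusted p = 0.695). Cyp7a1 lost its call without sham replicate 2 or any single IR replicate, and Baat without sham replicate 1 or 2 or IR replicate 1 or 2 (adjusted p up to 0.147). Cytochrome P450 and conjugation genes had a median of 0.38 (camera adjusted p = 0.0448, and adjusted p = 0.362 with an estimated correlation). It lay below 0 with scaling by library size alone, where the list did not pass camera (adjusted p = 0.0816). The only called gene of 26 (1 adjusted over the list alone) was Cyp2u1, which fell by 1.23 (SE 0.26), a call lost without sham replicate 1 or 2 or IR replicate 1 or 2 (adjusted p up to 0.0962). That list did not pass with the length correction (adjusted p = 0.134), nor without sham replicate 1, sham replicate 2 or IR replicate 3 (adjusted p up to 0.214). Hepatocyte secreted and identity genes had a median of 0.45 (camera adjusted p = 0.0038, and adjusted p = 0.476 with an estimated correlation). It lay below 0 with scaling by library size alone, where the list still passed camera (adjusted p = 0.0147). Of these 18 genes 1 was called (4 adjusted over the list alone), Vtn (0.86, SE 0.23), and not without sham replicate 1 or 2 or IR replicate 1 or 2 (adjusted p up to 0.200). Of 14 pericentral genes, Lgr5 (-2.19, SE 0.41) and Tbx3, linked to Wnt signalling, fell (3 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.669). Lgr5 lost its call without IR replicate 1 or 2 (adjusted p up to 0.0750). Of 14 periportal genes, Sds and Arg1 rose (4 adjusted over the list alone; camera adjusted p = 0.406).

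**Figure D4:**
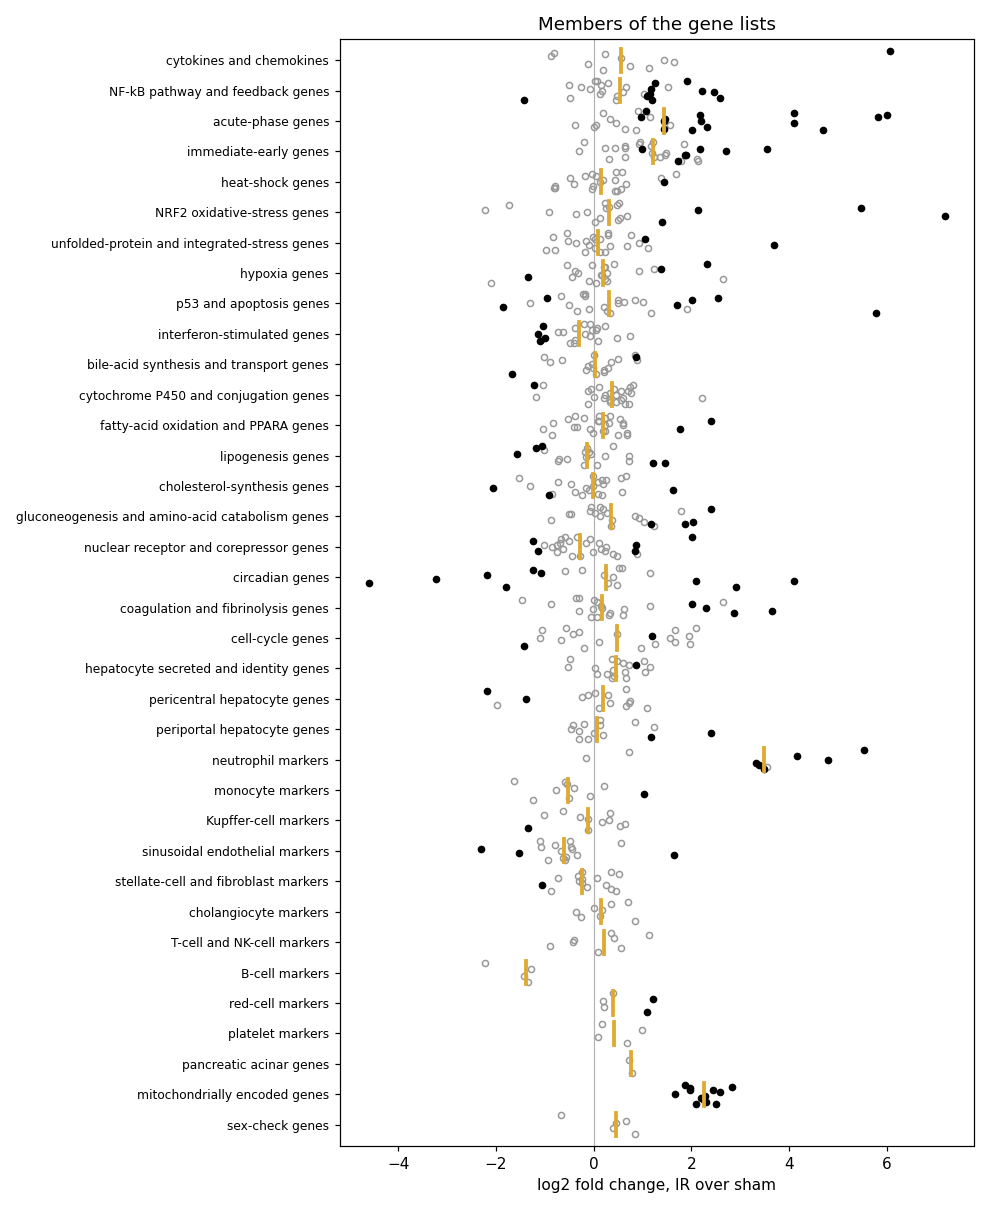
Log2 fold change (IR over sham, horizontal axis) of each tested member of the 36 lists, 1 row per list; filled points have an edgeR adjusted p under 0.05, open points do not, and the yellow bar is the list's median. Neutrophil markers (median 3.48), mitochondrially encoded genes (2.26) and acute-phase genes (1.44) lay to the right, and circadian genes spread to both sides.

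Called clock genes lay in both directions. Of 18 circadian genes, 6 fell and 3 rose (7 and 4 adjusted over the list alone), with a list median of 0.25, a mean of -0.12 and a camera adjusted p of 0.649. Per3 (-4.61, SE 0.34), Dbp, Per2 (-2.18), Tef (-1.79) and Hlf (-1.07) were among those that fell, and Npas2 (4.10, SE 0.56), Arntl (2.92) and Nfil3 (2.09) rose. Npas2 rested on 11 counts over the sham livers and 125 over the IR livers. Nr1d1 and Per1, other clock genes, were at 0.48 and 0.57 and did not pass. Of 27 nuclear receptor and corepressor genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.463). Cebpb, a transcription factor gene, rose by 2.02 (SE 0.30). Of 22 coagulation and fibrinolysis genes, 4 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.0612), led by Thbd (3.65, SE 0.39), which encodes thrombomodulin, and Thbs1 (2.87, SE 0.62; lost without sham replicate 2 or IR replicate 1, adjusted p up to 0.0913). Rrm2 (1.19, SE 0.22) rose and Ccnd1 fell by 1.42 (SE 0.35) among 19 cell-cycle genes (2 and 1 adjusted over the list alone; camera adjusted p = 0.463). Rrm2 lost its call without sham replicate 2 (adjusted p = 0.0817). Ccnd1 was not called with the length correction (-1.31, SE 0.36, adjusted p = 0.0612), and without sham replicate 3 alone among the single leave-outs did it keep its call (adjusted p up to 0.125).

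All 13 mitochondrially encoded genes were called higher (13 adjusted over the list alone; median 2.26, camera adjusted p = 3.67e-08, and adjusted p = 0.476 with an estimated correlation). ND6 rose most, by 2.84 (SE 0.45), which became 2.18 without IR replicate 1, 2.04 with the length correction and 1.45 with the length and GC corrections. It lies opposite ND5 and, with the strand of the counts not given, the reads of both cannot be told apart. Bcl3, Baat, Acaca, Sds, Dbp and Ccnd1 also overlap another counted gene. Of the 56 named genes called by edgeR, 26 kept their call and all 56 their sign whichever single library was left out, and the fold of 11 moved more than 1.5 times in at least 1 leave-out, those of Saa2, Mt1 and Ddit4 among them. With the length correction 3 folds moved as far and 6 genes lost the call, Cyp7a1 among them (-1.52, SE 0.44, adjusted p = 0.0733).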

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

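Settings that left out mitochondrially encoded genes or took out length and GC trends, and all settings for the list tests other than the estimated correlation and fry, were chosen after seeing the data. The numbers of higher and lower genes (585 and 489) and of those over 2-fold (494 and 405) stayed within 1.5 times with RLE scaling, limma-voom, a minimum of 1 CPM in 3 libraries, the length and GC corrections and without mitochondrially encoded genes. DESeq2 gave 1178 and 989, with 756 and 628 over 2-fold. In simulated data 21.7% of its calls were false, but only 197 genes were changed there, so this is not the share expected here. Library size alone gave 352 and 3159, with 297 and 2217. Without a low-count filter there were 888 and 822, with 660 lower over 2-fold. On log2(FPKM + 1) there were 282 and 2541, with 154 and 623; on log2(FPKM + 0.1) 277 and 2453, with 206 and 1362; and on log2(FPKM + 1) without a filter 167 and 988, with 84 higher over 2-fold. The last 3 and library size alone have no scaling factors by construction. Leaving out 1 library gave 192 to 1260 higher and 65 to 1187 lower genes, and 192 to 816 and 65 to 812 over 2-fold, with fewer livers per group.

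With the replicate number as a block, 154 genes were higher and 44 lower, and 154 and 44 over 2-fold. Same-numbered sham and IR livers did not deviate together (correlations -0.0936, -0.114 and -0.33), which gave no sign of pairing. These few values, over genes that move together, cannot exclude that the livers were paired. The block also takes up degrees of freedom.

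The number of lists past the threshold (11) was 8 to 14 with 1 library left out, 0 with an estimated correlation, and 7 and 30 in fry's directional and mixed tests, which do not compare a list with other genes. Medians of lists reversed only in settings without scaling factors. There the median of all genes was below 0 too. It was -0.51 with library size alone, -0.36 on log2(FPKM + 1), -0.44 on log2(FPKM + 0.1) and -0.049 without an FPKM filter. A list median below 0 can thus lie above that of all genes. With library size alone, the medians were -0.18 for NRF2 oxidative-stress genes, -0.18 for p53 and apoptosis genes, -0.099 for cytochrome P450 and conjugation genes, -0.11 for gluconeogenesis and amino-acid catabolism genes, -0.32 for coagulation and fibrinolysis genes and -0.026 for hepatocyte secreted and identity genes. On log2(FPKM + 1) they were -0.12 for cytokines and chemokines, -0.037 for NF-kB pathway and feedback genes, -0.14 for p53 and apoptosis genes, -0.070 for cytochrome P450 and conjugation genes, -0.11 for gluconeogenesis and amino-acid catabolism genes and -0.035 for hepatocyte secreted and identity genes, and on log2(FPKM + 0.1) -0.087, -0.041, -0.15, -0.070, -0.11 and -0.035. Without an FPKM filter they were -0.00067 for NF-kB pathway and feedback genes, -0.045 for NRF2 oxidative-stress genes, -0.070 for cytochrome P450 and conjugation genes, -0.11 for gluconeogenesis and amino-acid catabolism genes and -0.035 for hepatocyte secreted and identity genes. The cause was not tested further than the shift of all genes given above. Of 1212 values of the 65 named genes in other settings, 1025 kept their side of the threshold, 179 lost the call, 8 gained it and none reversed; 10 changed sign with no call in either setting. Of 675 list medians, 617 kept their side, 14 lost and 21 gained it, 23 reversed, and 81 of the first changed sign without a call. In simulated data with 3 livers per group, edgeR recovered 15.2% of 2-fold changes and DESeq2 33.3%, so many changes of this size may be missed. Other numbers of livers or depths were not simulated.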

Other observations

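Tests written after the results they measure were seen were those on the time of day, on loss of clock-driven transcription, on the mitochondrially encoded genes against genes of like length, on a response of short genes to IR alone, and on a mislabelled or a fed sham replicate 3. The other tests were written before.

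Targets of the glucocorticoid receptor, from a list of 10 written before their values were looked at, but after Tat and other steroid-responsive genes had been seen to rise, had a median log2 fold change of 1.33 (camera adjusted p = 9.66e-05 over this list and the 36 fixed lists, and adjusted p = 0.180 with an estimated correlation, where the list does not pass; unadjusted 1.31e-05 and 0.0223). In edgeR's test, 5 of the 10 were higher and 0 lower (8 and 0 adjusted over the list alone). Fkbp5, which encodes a chaperone of the receptor, rose by 1.25 on the log2 scale (SE 0.26), Zbtb16 by 2.49 (SE 0.62) and Mfsd2a by 1.80 (SE 0.20), while Cdkn1c was at -0.11. A stronger glucocorticoid signal after IR is a hypothesis that these values leave open, and several of these genes also respond to fasting and no hormone was measured here.

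Clock genes fell and rose side by side, with Per3 and Dbp lower and Npas2 and Arntl higher. With library size alone, 9 of the 9 called clock genes kept call and sign. That setting lowers all genes (median log2 fold change -0.51), so it is no check on the 6 that had fallen. The 3 that rose kept their call against this shift. A scaling factor moves all genes of a library alike, so library scaling as the source of both directions is argued against. A loss of all transcription driven by CLOCK and BMAL1 is not settled. Nr1d1, Ciart and Per1 had a median log2 fold change of 0.52 (largest SE 0.374), but they were picked after their values were seen. Of these genes, Nr1d1 and Per1 did not pass edgeR's test, and other clock genes such as Per3 and Dbp fell, so this median cannot decide the question. A difference in the time of day at collection stays open. A cosine of approximate peak hours explained 49.1% of the variance over 18 genes (permutation test, p = 0.00511). The peak hours were taken from general knowledge after the fold changes were seen. The log2 fold change of Nr1d1 lay 3.70 above that of Dbp, although their peak times are neighbouring. This is 1 pair of genes, and the fit used peak times without the size of each gene's daily swing. The difference thus does not decide for or against a plain shift in time. A response of the clock to IR itself may also shift clock genes and was not tested.

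In the comparison of the groups, short genes and mitochondrially encoded genes were higher in IR. For short genes this did not hold in each library. In the shortest bin of genes, the median deviation was 0.0092 in IR replicate 3 and 0.106 in sham replicate 3. Length-dependent recovery of transcripts as the whole cause of the calls is argued against, since 75.5% of calls kept call and sign when the length trend was taken out. The mitochondrially encoded genes had a median 1.77 above that of nuclear genes of like length. The length trend of nuclear genes thus does not account for their whole rise. This difference was above the 99th percentile of random length-matched sets. The mitochondrially encoded genes move together (estimated correlation 0.848), unlike genes drawn at random, so that percentile does not serve as a p-value. GC content did not account for the length trend, whose rho was -0.298 before and -0.316 after the GC trend was taken out, over genes with known GC content. A response of short genes to IR alone stays open: rho was -0.352 between sham replicate 3 and the other sham livers and -0.155 between IR replicates 1 and 2 and IR replicate 3, but the first rests on 1 library picked for its short genes and the second may be a stronger response to IR. RNA quality was not measured in these tables.

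Sham replicate 3 stood apart from the other sham livers. Length-dependent recovery is argued against, since its spread against them stayed 2.17 times the spread between them (2.5 before) once the length trend was taken out. Over 2410 genes called without it, it lay at 0.447 on a scale from the other sham livers (0) to the IR livers (1), and IR replicate 3, measured likewise, lay at 0.546, so a wrong label cannot be told apart from a liver unlike its group on this value, which falls between the bounds set for it. Over 24 acute-phase and neutrophil genes called without it, it lay at 0.0351 (upper quartile 0.268), and IR replicate 3 lay at 0.807 over the 19 such genes called without that library, which argues against an IR liver with the response of the others, or a swap of these 2 livers. A fed state is not settled: relative to the other sham livers, the median of the lipogenesis list lay 0.741 above that of the fatty-acid oxidation list (0.205 and -0.536), but the gluconeogenesis list lay at 0.163, and cholangiocyte (-1.23), B-cell (1.18) and sinusoidal endothelial (-0.957) markers lay further away.

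The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the counts of genes higher (585), lower (489), higher over 2-fold (494) and lower over 2-fold (405), 1 of the 10 splits reached the value, the real one, and edgeR called 0 genes in the others. Those others had 86 to 2549 genes at an unadjusted p under 0.05, and DESeq2 called 0 to 729 in them. The split with 2549 and 729 exchanged sham replicate 3 with IR replicate 3. For the 11 lists past the threshold, 4 of the 10 splits gave as many, and the highest other gave 14, so the number of lists called with the preset correlation was not above that of regrouped livers.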
